A study of Drosophila melanogaster with 2 samples.

How the data were processed

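The series measured gene expression on 2-colour oligonucleotide arrays of *Drosophila melanogaster*, in which RNA of an endocycling larval tissue was labelled with Cy3 and RNA of brain and imaginal disc complexes with Cy5, per the labels' protocols. Tissue was dissected by hand from wild-type yw larvae in the third instar, 70 to 75 hours after egg laying. The RNA was amplified and labelled through amino allyl coupling, and slides were read with a GenePix scanner and its image software, per the labels' protocols and the design text. The table used here holds 1 column for salivary gland against brain-disc and 1 column for fat body against brain-disc, with 14532 probes in each.

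Each column was deposited as the authors' mean log ratio over biological replicates, 3 for the salivary gland and 2 for the fat body, per the labels. The labels point to a supplementary file with the values of each experiment, which was not analysed here, so no standard deviation, standard error or p-value could be attached to the value of a probe, and differences are reported by size alone. The background correction, the normalization within or between arrays, the centring and the filter behind the missing values are not given in the sources used here. The log base is not given either. The values were read as log2, since sizes up to 17.2 in natural or decimal logs would lie far beyond a scanner of 16 bits, whose full range is 16.0 on the log2 scale, and even as log2 the largest values pass it.

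The direction of the deposited log2 ratio is not stated either. The titles name the endocycling tissue before brain-disc, which puts it in the numerator, whereas image software of this kind often writes red over green, which would put brain-disc there. Before the data were examined, the order in the titles was fixed as the likely direction, to be checked with marker genes of each tissue. That check could not be made, because the probe IDs could not be paired with genes. A positive value is therefore read as likely higher in the endocycling tissue, and every statement of higher or lower turns around if the ratio runs the other way. The scale, the centring and the direction all remain unstated. The median over all values was -0.22 in the salivary gland column and -0.18 in the fat body column.

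The probe IDs name a source plate, a row letter and a column number. None was found among the identifiers, symbols, synonyms and accessions of the 17872 genes in the RefSeq gene table of *D. melanogaster*, so 0 of 14532 probes have a gene name here. The lists of cell cycle, DNA replication, apoptosis, secretory, metabolic and tissue marker genes fixed before the data were examined could not be applied. For the same reason probes of a gene could not be averaged, and the unit of every count is the probe. The fixed naming rule ranked probes past the threshold in the same direction in both columns by the smaller of their 2 sizes. Only the 2 leading probes in each direction are named, since an ID without a gene says little.

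Counts used a threshold of 2-fold, a log2 value of 1 or more in size, on values as deposited and on the 4391 probes with a value in both columns. The number of probes shared by both columns was set beside n1 × n2 / N, the overlap of independent lists. Both columns have brain-disc tissue as comparator and the same assignment of dyes, and each can add to any overlap, same-sign share or correlation. Since dye goes with tissue in the labels' protocols, a dye effect on a probe could not be told apart from a tissue difference. The chance level that a shared comparator gives with no effect was not simulated, because the spread between arrays is not known from averages. The salivary gland value minus the fat body value of a probe was used to compare the 2 tissues. The brain-disc term would cancel in it only if both sets of arrays held the same brain-disc levels on 1 scale, which was not tested, and column position accounted for more of the rank variance of the difference (5.82%) than of either column (3.01% and 2.33%). Alternatives fixed before the data were examined were a centring of each column on its median over all its values, the same centring with a scaling by the median absolute deviation, thresholds of 1.5-fold and 3-fold, and all probes of a column. A shift that brings all position classes of the probe IDs to 1 median, the centring on probes with both values, and a restriction to probes shown to be full averages were added after seeing the data.

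The number of arrays behind a value was read from its last digits. Single values have 3 decimals, so a mean of 3 arrays ends in a repeating fraction for about 2 of 3 probes, and a mean of 2 arrays ends in an added digit, a 5, for about 1 of 2 probes. Values within 5e-07 of these patterns, or within a wider margin for the repeating fractions, were counted, and the number of averages was estimated from them. On 20000 simulated means the estimated totals came to 100.2% of the true number of means of 3 and 100.4% of that of means of 2. The counting of probes was also tested on simulated data, which tests the code and says nothing of the error of the calls.

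Position effects were tested with the share of rank variance between position classes and 100000 permutations of the positions, 10 tests in all with Benjamini-Hochberg adjustment. Tests of position were not in the plan fixed before the data were examined. The direction of the trend in each of 38 full source plates was tested with a two-sided exact sign test, 11 tests in all. Intervals on percentages of probes are exact 95% Clopper-Pearson intervals and cover counting error alone. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.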

Results

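Expression was compared between endocycling and mitotically cycling tissue of the *Drosophila* larva. Cells in the endocycle replicate their DNA repeatedly without dividing and become polyploid. The larval salivary gland, a secretory organ, and the larval fat body, a storage and metabolic organ, both grow in this way. The brain and imaginal discs, which form the adult nervous system and appendages, contain dividing cells and served as the comparator on each array. The design asks which transcripts differ between endocycling and mitotic tissue, and which differences the 2 endocycling tissues have in common. The type of cell cycle goes with the organ in both columns. A difference that belongs to the cycle therefore cannot be told apart here from one that belongs to the organs. The data are 2 columns of mean log2 ratios, averaged by the authors over 3 biological replicates for the salivary gland and 2 for the fat body. No replicate values were used, so none of the values below carries an error, and no difference could be set against the spread between replicates.

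Of 14532 probes, 8026 (55.2%) had a salivary gland value and 4893 (33.7%) had a fat body value. Both values were present for 4391 probes and neither for 6004. Salivary gland values ranged from -9.51 to 17.2, with a quartile range of -1.24 to 0.89. Fat body values ranged from -8.97 to 16.999, with a quartile range of -1.13 to 1.01. The number of averaged arrays differed between probes. From the last digits of the values, about 3920 salivary gland values were means of 3 arrays, about 2180 were means of 2 and about 1926 (23.99%) came from a single array. In the fat body column about 4622 values were means of 2 arrays and about 271 (5.54%) came from 1. Probes with both values were better replicated: an estimated 7.65% of their salivary gland values and 2.85% of their fat body values came from 1 array.

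Salivary gland and brain-disc differed by 2-fold or more in 729 shared probes (16.6%) with values at or above 1 and in 1607 (36.6%) with values at or below -1. With the direction that the order of tissues in the titles makes likely, the first set was higher in the salivary gland and the second was higher in brain-disc. The 10 highest of these probes lay between 6.32 and 10.3 on the log2 scale, and the 10 lowest between -9.51 and -5.44. Negative values made up 68.8% of the probes past 2-fold. This split depended on the probes and on the zero point. Over all 8026 salivary gland values it was 57.1%, with 1832 positive and 2440 negative probes. After the planned centring on the median over all salivary gland values, it was 60.8%, with 864 positive and 1342 negative shared probes. After centring on the median of the shared probes, -0.52, it was 48.5%, with 1101 positive and 1035 negative probes.

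Fat body and brain-disc differed by 2-fold or more in 786 probes (17.9%) with positive values, likely higher in fat body, and in 1342 probes (30.6%) with negative values. The 10 highest shared probes lay between 7.58 and 13.2, and the 10 lowest between -8.97 and -5.89. Negative values made up 63.1% of the probes past 2-fold. Over all 4893 fat body values they made up 52.4%, since 1234 probes were positive and 1359 negative. After the planned centring on the median over all fat body values, they made up 56.5% among the shared probes. After centring on the median of the shared probes, -0.33, they made up 50.1%. The positive side of the fat body column reached further than the negative side, with the 5th percentile of all values at -2.66 and the 95th at 5.77. The corresponding percentiles of the salivary gland column were -2.96 and 3.31.

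Salivary gland and fat body values had the same sign at 3441 of the 4391 shared probes (78.4%), against 53.2% for independent columns with the same shares of positive and negative values. Of the shared probes, 467 were at or above 1 in both columns and 994 were at or below -1 in both. Independent lists of these sizes would share 130 and 491 probes, so the observed overlaps were 3.58 and 2.02 times as large. Which direction held more common probes depended on the zero point. After the planned centring of each column on its median over all its values, 548 were positive and 804 negative in both. After each column was centred on its median over the shared probes, 673 were positive and 629 negative in both. Of the probes positive past 2-fold in the salivary gland, 64.1% were also positive past 2-fold in the fat body. Of those negative past 2-fold in the salivary gland, 61.9% were also negative past 2-fold in the fat body. Opposite calls were rare, with 43 probes negative in the salivary gland and positive in the fat body and 15 the other way, against 288 and 223 for independent lists. Across the 4391 probes, which are not independent replicates, Pearson's r was 0.76 and Spearman's rho 0.72, with a covariance of 2.66. Both columns have brain-disc tissue as comparator and the same assignment of dyes. Part of the same-sign share, the overlap and the correlation may come from that shared arm or from the dyes. The size of that part was not estimated, and independent lists and columns leave it out.

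**Figure D1:**
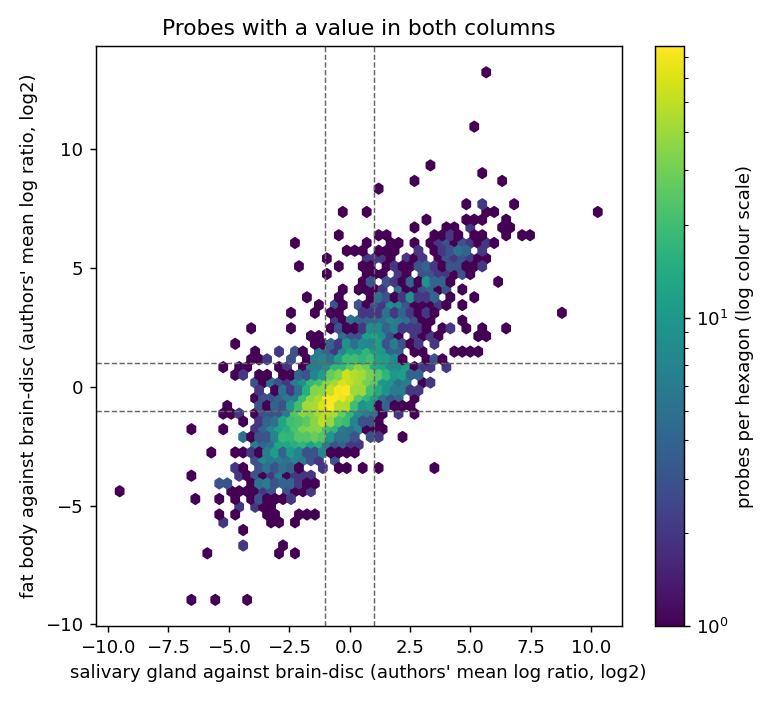
Mean log2 ratio of fat body against brain-disc (vertical axis) plotted against that of salivary gland against brain-disc (horizontal axis) for the 4391 probes with both values; colour gives the number of probes per hexagon on a log scale and dashed lines mark 2-fold. Most probes lie along a rising band, with 994 probes in the lower left and 467 in the upper right corner beyond the dashed lines. With each column centred on its median over all its values, these corners would hold 804 and 548. With each column centred on the shared probes, they would hold 629 and 673.

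The sets common to both tissues differed in how evenly they moved. The 994 probes negative in both had medians of -2.06 in the salivary gland and -1.94 in the fat body, and 74.9% of them lay within 2-fold of each other. The 467 probes positive in both had medians of 2.42 in the salivary gland and 3.56 in the fat body. Of these, 361 (77.3%) were larger in the fat body and 46.0% lay within 2-fold of each other. Over all shared probes the fat body column also reached further up, with a 95th percentile of 3.94 against 2.76 in the salivary gland. The common sets were not compared after rescaling the columns. At 16-fold or more in both tissues, 84 probes were positive and 25 were negative. The probes with the largest common positive values were DAC032G23, at 10.27 in the salivary gland and 7.46 in the fat body, and DAC038M15, at 6.76 and 7.82. The largest common negative values were those of DAC019N19, at -6.43 and -8.97, and DAC029D05, at -5.84 and -7.16. The fat body value of DAC019N19 is the lowest of its column and is shared by 3 probes. No gene name is available here for these probes.

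Salivary gland and fat body were then compared with each other through the difference of their columns. The difference lay within 2-fold for 2805 of the 4391 probes (63.9%), at or above 1 for 547 (12.5%, likely higher in the salivary gland) and at or below -1 for 1039 (23.7%, likely higher in the fat body). Its median was -0.21, with a salivary gland median of -0.52 and a fat body median of -0.33 over the same probes. The 10 probes most in favour of the salivary gland lay between 3.94 and 6.70, and the 10 most in favour of the fat body between -8.49 and -6.12. After the planned centring of each column on its median over all its values, 570 and 989 probes passed 2-fold. After each column was centred on its median over the shared probes, 707 and 819 probes passed 2-fold. When all 48 position classes of the probe IDs were shifted to 1 median, 592 and 893 did.

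Probes with a value in 1 column alone differed from the shared probes. The 502 probes with a fat body value and no salivary gland value had a median of 4.99, and 448 of them (89.2%) were at or above 1, whereas the shared probes had a fat body median of -0.33. The 3635 probes with a salivary gland value alone had a median of 0.20, with 1103 (30.3%) at or above 1 and 833 (22.9%) at or below -1. Among fat body values of 4 or more, 365 of 580 (62.9%, exact 95% interval 58.9 to 66.9%) lacked a salivary gland value. Among fat body values of -4 or less, 0 of 82 did, with an upper limit of 4.40%. In the salivary gland column, 164 of 267 values of 4 or more (61.4%, 55.3 to 67.3%) and 46 of 109 values of -4 or less (42.2%, 32.8 to 52.0%) lacked a fat body value. Counts over shared probes therefore leave out most of the strongest positive fat body values.

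**Figure D2:**
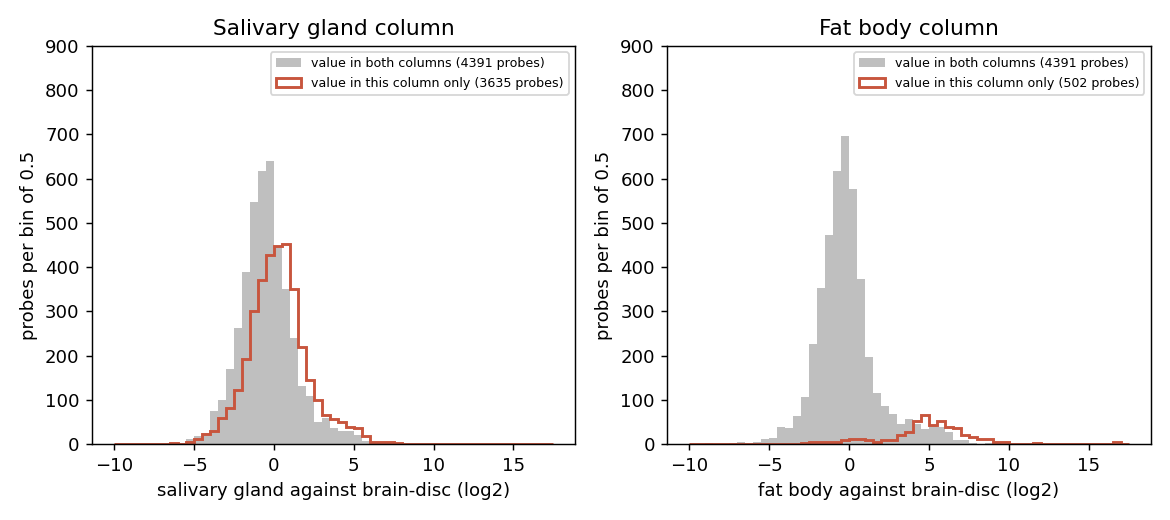
Histograms of the mean log2 ratios of the salivary gland column (left) and the fat body column (right), in bins of 0.5, for the 4391 probes with both values (grey) and for probes with a value in that column alone (red outline). The 502 probes present in the fat body column alone centre on 4.99, far to the right of the shared probes.

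Values and missing values also followed the column number in the probe ID, in a pattern that restarted at column 13. The median salivary gland value was lowest at position 3 of the 12 (-0.65) and highest at position 12 (0.43). The median fat body value was highest at position 1 (0.25) and lowest at position 8 (-0.46). The share of probes with a salivary gland value reached 72.1% at position 12 against 46.1% at position 2, and that with a fat body value fell from 44.9% at position 1 to 24.8% at position 12. All 5 measures tested by column position gave a permutation p of 1e-05, the smallest that 100000 permutations can give, and 1.67e-05 after adjustment. By row letter, with a period of 4, the same measures differed less: the share with a fat body value ran from 29.45% to 38.03% (permutation p 1e-05, adjusted 1.67e-05), and the medians spanned 0.21 in the salivary gland column (adjusted permutation p 0.00034) and 0.22 in the fat body column (0.0025). The share with a salivary gland value ran from 52.5% to 57.5% by row letter (adjusted permutation p 0.0004), and the difference between the columns did not pass (permutation p 0.095). Column position accounted for 3.01% of the rank variance of the salivary gland values, 2.33% of that of the fat body values and 5.82% of that of their difference. The share of salivary gland values at or below -1 was 39.0% at position 3 and 14.5% at position 12. When all 48 position classes were shifted to 1 median, the salivary gland counts were 762 positive and 1508 negative and the fat body counts 772 and 1322, and 87.0 to 91.2% of the probes called before remained called.

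**Figure D3:**
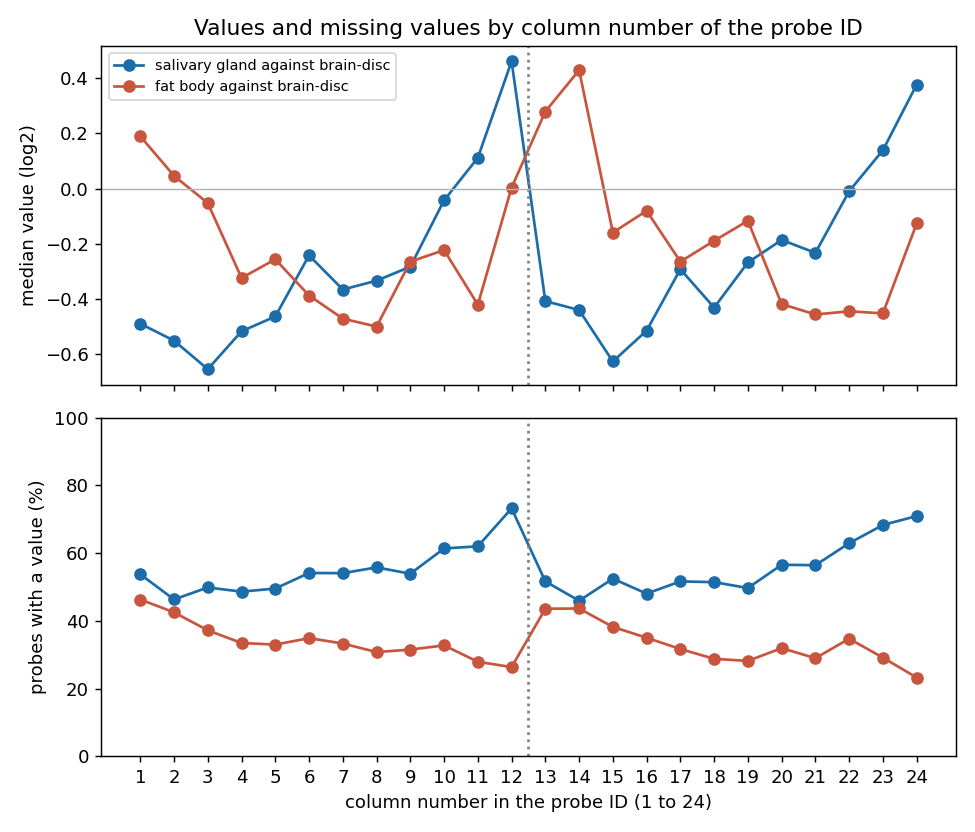
Median log2 ratio (upper panel) and percent of probes with a value (lower panel) by the column number in the probe ID, 1 to 24, for the salivary gland (blue) and fat body (red) columns; the dotted line separates columns 12 and 13. The salivary gland median rises from -0.65 at column 3 to 0.46 at column 12, falls back at column 13 and rises again to 0.38 at column 24.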

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

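The tests of array position, by source plate and among the fat body probes, and of averaging were chosen before their results were seen, and the other tests in this part only after.

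The values follow the column number of the probe ID with a period of 12. This pattern was first seen in these same values. The test by plate shows how widely it repeats and is not independent support for it. In 37 of 38 full source plates (97.4%) the salivary gland values rose with column position (median Spearman's rho 0.15, two-sided exact sign test p = 2.84e-10, 1.04e-09 after adjustment), and in 34 of 38 the fat body values fell (median rho -0.13, exact p = 6.04e-07). An order of genes on the plates that acted alike on both columns is argued against, because the salivary gland value minus the fat body value of the same probes still spanned 0.74 on the log2 scale between positions. The repeat in nearly every plate, with a restart at column 13, could come from a gradient across the printed array that remains in the deposited values. A plate order that follows differences between the 2 tissues was not tested and stays open, and the layout of the printed array is not given in the sources used here.

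Fat body values of 1 or more without a salivary gland value numbered 448, a signal outside the comparison of shared probes. A source confined to some column positions is argued against, since the lowest of the 12 position medians of the 502 fat body probes was 4.01. Row position was not tested for them. Single-array values alone are argued against as the source, since the 178 probes shown to be means of 2 arrays had a median of 4.63. A mean of 2 can still rest on 1 extreme array, which cannot be checked without replicate values. Whether these values are signal from fat body RNA, and so whether positive means higher in the fat body, cannot be told apart from the opposite direction. In the salivary gland column, probes without a fat body value lay 0.63 above those with both values (median over 12 positions, bootstrap 95% interval 0.50 to 0.75). An estimated 43.7% of the former values came from 1 array, against 7.65% of the latter. Values of 4 or more lacked a fat body value 19.2 percentage points more often than values of -4 or less, just under a cutoff set after the data were seen. Neither this nor the other percentages of missing values in this paragraph were taken within column positions, which values and missing values both followed. Brain-disc RNA was on both sets of arrays. By the order in the titles it is high at -4 or less, where 46 of 109 salivary gland values (42.2%) lacked a fat body value. Of all salivary gland values, 54.7% had one. With the direction turned it is high at 4 or more, where 61.4% lacked one. In the fat body column, 62.9% of values of 4 or more and 0 of 82 of -4 or less lacked a salivary gland value, while 89.7% of all had one. Missing values were thus more frequent at the positive end in both columns. At 2-fold, 60.2% of salivary gland values of 1 or more and 34.1% of those of -1 or less lacked a fat body value. In the fat body column, 36.3% and 1.25% lacked a salivary gland value. More missing values at the positive end go with the order in the titles if missing values mean weak signal, but the filter behind them is not known.

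Salivary gland values of 1 or more without a fat body value numbered 1103, again outside the shared probes. Opposite calls past 2-fold stood at 43 probes (negative in the salivary gland, positive in the fat body) and 15 probes (the other way), and the difference was not tested. Of the 48 probes of source plate c01, 41 had a salivary gland value, from -0.94 to 0.59, and 0 had a fat body value, whereas the other plates had fat body values for 19.0 to 47.1% of their probes.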

How the results depend on the processing

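No paired analysis was possible because each comparison was analysed as 1 averaged column, and no replicate was left out, since replicate values were not used here. Of 36 planned results under other settings, 25 stayed within 1.5 times the reported count and 11 did not. At 3-fold the salivary gland counts were 471 positive and 971 negative, the fat body negative count was 804, the count negative in both was 537, and the difference between tissues gave 260 and 498 probes. At 1.5-fold that difference gave 954 and 1568. Over all probes of a column, the salivary gland counts were 1832 and 2440 and the fat body positive count 1234. Centring on the shared probes, chosen after seeing the data, gave 1101 positive and 1035 negative salivary gland probes and 673 positive and 629 negative in both. These follow from the stricter or looser threshold, the added probes and the moved zero. The overlap stayed above that of independent lists under all settings run on shared probes, by 2.68 to 5.29 times for positive and 1.68 to 3.02 times for negative probes. Every setting keeps the same correlated columns, comparator and dyes, so an excess was likely under each and its source was not tested. In the 1030 probes shown to be means of 3 and 2 arrays, 9.13% were positive in both (10.6% over all shared probes), 22.9% negative in both (22.6%) and 0.87% opposite (1.32%), and r was 0.78. Genes with a single probe, a leading probe per gene and the gene lists were not run, for want of gene names. Precision is limited by the few arrays averaged, and no signal over background is known.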

Other observations

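Of the shared probes, 103 were at 4 or more in the salivary gland and 215 in the fat body, and 84 were in both lists (81.6% of the first and 39.1% of the second), against 5.04 for independent lists. At -4 or less, the lists held 63 and 82 probes with 25 in common (39.7% and 30.5%), against 1.18. These counts cover shared probes alone and were made after the values had been seen. They share the brain-disc comparator and the assignment of dyes, which the independent lists leave out.

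Some extreme values repeat exactly. The fat body maximum, 16.999, stands at 3 probes, none with a salivary gland value, and the fat body minimum, -8.97, stands at 3 probes, each with a salivary gland value. The salivary gland maximum, 17.2, and minimum, -9.51, each occur at 1 probe.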
